A study of Homo sapiens with 12 samples.

How the data were processed

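Expression was measured on Illumina BeadChips in 12 RNA samples from a pair of isogenic HEK293 lines, one stably expressing the wild-type glucocorticoid receptor (wtGR) and the other a receptor that cannot be SUMOylated (GR3KR). All samples received 100 nM dexamethasone, and 6 of them also received 5 µM 15d-PGJ2, for 6 h. Each of the 4 groups holds 3 arrays, and no sample went without dexamethasone.

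The deposited table of bead signals gives a linear intensity per probe and array, not normalized and with no background subtracted. The same deposited table gives a detection p-value for each intensity, in even steps from 0 to 1. A further deposited table holds log2 values that were made with lumi, per the submitters' processing notes, which give neither its version nor its steps. All tables hold 47312 probes for the 12 samples, and columns were matched to samples by the identifiers in their headers.

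The intensities were background corrected, quantile normalized and put on a log2 scale with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16. The deposited table has no control probes, so the background was inferred from the detection p-values. Kept were 20909 probes with a detection p-value under 0.01 on at least 3 of the 12 arrays. Gene symbols came from the probe annotation, which gives 1 symbol for 30107 probes, several for 8 and none for 17197. Of the kept probes, 16339 had 1 symbol and 4570 did not and were left out. Comparing the symbols with a RefSeq gene table changed 0 of them, and 47 probes had a gene identifier that the table lacks. Each of the 12337 genes was read by its kept probe with the highest mean over the 12 arrays. Where a gene had other kept probes, they were compared with the probe in use. No genome coordinates were used. Near-identical genes such as HSPA1A and HSPA1B, HSPA6 and HSPA7, GSTM1 and GSTM2, the metallothioneins and the histones can share signal between their probes.

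A linear model with 4 group means was fitted to each gene with lmFit and eBayes of limma, with 8 residual and 2.97 prior degrees of freedom. The 5 comparisons were the 15d-PGJ2 effect in each line, the difference of these effects (GR3KR minus wtGR), and GR3KR minus wtGR without and with 15d-PGJ2. Tests were 2-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 12337 genes. Errors beside log2 differences are standard errors of the model, and errors beside group means are standard deviations of 3 arrays. Where arrays of the dimmer group lay below detection, their values were raised to the lowest detected level of each array and the fold is given as "at least". No fold is given where no difference was left, or where an array of the brighter group lay below detection. Correlations of effects were computed across genes and have no p-value, since genes are not independent replicates. The labels call the arrays triplicates, and nothing states that they come from separate cultures, so p-values measure only the spread between these samples. Array precision is limited by their number.

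A total of 22 gene lists were fixed before the data were examined, as were the comparisons, the tests and the other processing settings tried, except where stated. They are glucocorticoid receptor targets, metallothioneins, NRF2 targets, HSF1 heat shock targets, endoplasmic reticulum (ER) chaperones, ATF4 integrated stress response genes, NF-kB inflammatory targets, immediate early genes, sterol synthesis genes, PPAR targets, p53 targets, proteasome subunits, the SUMO machinery, S phase genes, G2/M genes, hypoxia targets, YAP and SRF cytoskeletal targets, ribosomal proteins, canonical histones, and fibroblast, leukocyte and neuronal markers. They hold 449 genes, of which 13 stand in more than 1 list. The 20 lists with at least 5 measured members were tested with camera of limma, with its preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists within a comparison. Each list was also tested with a correlation estimated from the data and with fry of limma, which asks whether the members move one way on balance and makes no comparison with other genes. Counts of called members are given over all genes and adjusted over the list alone.

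The genes to name were set by rule. For each 15d-PGJ2 effect these were the 10 largest changes in each direction among called genes whose treated and control arrays did not overlap. For each other comparison they were the 8 largest called changes in each direction. For each list described in a comparison they were up to 4 called members with the largest change, or up to 2 with the smallest p where none was called. Genes without an established name were counted and not named. Which lists had members named was narrowed after the list results were seen, to the lists called in a comparison, to the lists called in wtGR cells for the effect in GR3KR cells, and to glucocorticoid receptor targets throughout.

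Array quality was checked by the number of probes detected and by how far probes of the same gene disagreed. For 3228 genes with 7230 kept probes, each probe was centred on its gene's mean on each array and then on its own mean, and the main axis of what was left took 71.4% of the variance (the second took 15.6%). The position of each array on this axis is called the probe disagreement index. After the data were seen, 3 alternatives were added: leaving out GR3KR 15d-PGJ2 arrays 1 and 2, the index as a covariate over 12 arrays, and both together with an index computed over the 10 arrays left (69% of the variance).

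Other settings tried were the lumi values, no background correction, an offset of 50, cyclic loess or median scaling in place of quantile normalization, a detection p-value limit of 0.05 or no filter, every kept probe tested by itself, eBayes with trend and robust, array weights, the replicate number as a block, only the groups of the comparison, a fold of at least 1.5, an adjusted p under 0.01, only called genes for the correlation of effects, and leaving out each array in turn. A block for the BeadChip was planned and not run, since the tables give no chip. The fits were tested on simulated data made by adding known changes to 200 of the 12337 genes. In the wtGR 15d-PGJ2 effect 2% of 50 genes changed by 1.5-fold were called, 42% at 2-fold, and 90% at 4-fold and at 8-fold, with 5 false among 117 calls. In the difference of effects the shares were 0%, 14%, 68% and 90%, with 5 false among 91 calls. These counts are of simulated data and give no rate of false calls on the real arrays, which differed in quality. There, setting wtGR dexamethasone array 1 with wtGR 15d-PGJ2 arrays 1 and 2 against the other wtGR arrays gave 213 calls. The real grouping gave 27.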

Results

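The data are bead signals of 47312 probes on 12 arrays, 3 for each of 4 groups: wtGR cells with dexamethasone, wtGR cells with dexamethasone and 15d-PGJ2, and the same pair for GR3KR cells. 15d-PGJ2 is an electrophilic prostaglandin, and dexamethasone is a synthetic agonist of the glucocorticoid receptor. HEK293 is a human embryonic kidney line. The series title places the question in whether 15d-PGJ2 alters glucocorticoid signalling through SUMOylation of the receptor, so the comparisons are the response to 15d-PGJ2 in each line, the difference between these responses, and the lines against each other.

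The arrays differed in quality within the design. GR3KR 15d-PGJ2 arrays 1, 2 and 3 detected 15223, 14207 and 17032 probes, and the other 9 arrays between 17959 and 19950. Median signals ran from 58.3 to 89.6. The probe disagreement index was -0.608, -0.551 and -0.143 on the 3 GR3KR 15d-PGJ2 arrays and -0.13 on wtGR dexamethasone array 3, against 0.0848 to 0.246 on the other 8. One ACTB probe (ILMN_1777296) read a log2 intensity of 5.10, 4.86 and 5.91 on the 3 GR3KR 15d-PGJ2 arrays and 5.85 on wtGR dexamethasone array 3, while the other ACTB probe stayed between 13.05 and 14.24 on all 12. Every comparison that uses the GR3KR 15d-PGJ2 group is therefore also given without arrays 1 and 2 or with the index as a covariate, alternatives chosen after the data were seen. The index on the 3 GR3KR 15d-PGJ2 arrays lay below that of every GR3KR dexamethasone array. As a covariate over 12 arrays it can therefore take out a response to 15d-PGJ2 together with array quality. A call lost with it is not thereby shown to be technical.

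**Figure D1:**
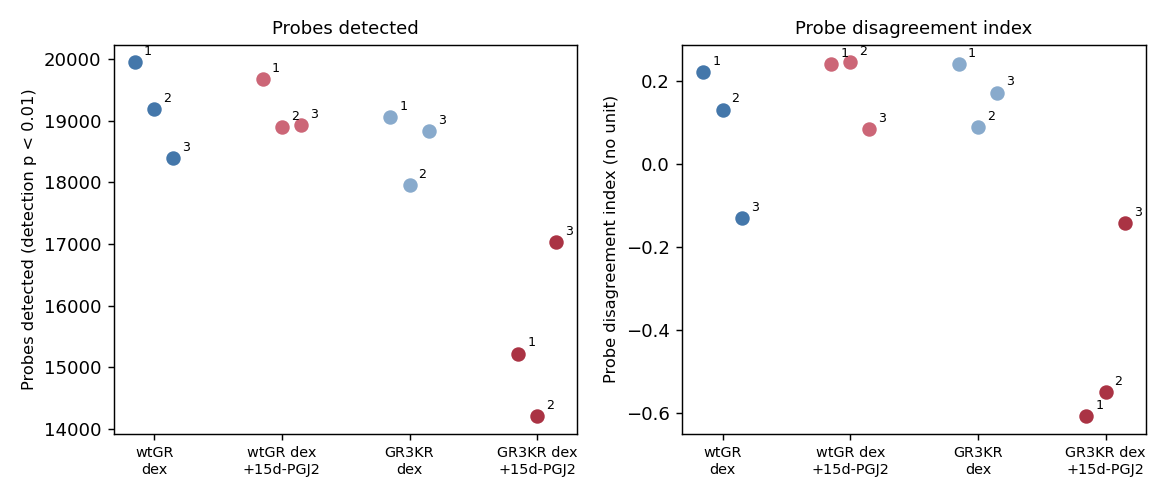
Probes detected per array and the probe disagreement index per array, by group, each point an array. GR3KR 15d-PGJ2 arrays 1 and 2 detected 15223 and 14207 probes and have index values of -0.608 and -0.551, below the 10 other arrays in both measures.

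The receptor's own gene, NR3C1, was read by 1 kept probe (ILMN_2389347), with log2 intensities from 5.42 to 6.28 over the 12 arrays and detection on 10 of them. Its other probes were detected on 0 and 2 arrays. Whether these probes lie within the introduced receptor sequence is not given, so the receptor's level in the lines cannot be read from them.

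In wtGR cells, 15d-PGJ2 raised heat shock genes and HMOX1. HSPA6, a stress-inducible HSP70 chaperone, rose 53.3-fold, from a log2 intensity of 7.51 ± 0.22 to 13.25 ± 0.24 (SD, n = 3 arrays in each group; limma adjusted p = 5.97e-07). Its near copy HSPA7 rose 22.3-fold, HSPA1B 14.2-fold and HSPA1A at least 5.62-fold. HMOX1, which encodes the haem-degrading enzyme haem oxygenase 1, rose 6.86-fold (log2 difference 2.78, SE 0.18, adjusted p = 2.1e-05). All of these were higher on all 3 treated arrays than on any of the 3 controls, which the rule for naming genes required.

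The other named increases were of CRYAB (3.69-fold), HSPH1 (3.62-fold), DEDD2 (3.15-fold), BAG3 (3.07-fold) and ZFAND2A (2.91-fold), of which CRYAB, HSPH1 and BAG3 encode chaperones or their partners. Fewer genes fell. The noncoding MIR503HG was 4.61-fold lower (log2 difference -2.20, SE 0.23, adjusted p = 0.00252), SNORA12 3.93-fold, SFRP2, a secreted Wnt modulator, 3.3-fold, the potassium channel KCNA5 3.06-fold, the interferon-induced IFIT1 at least 2.71-fold and the iron exporter SLC40A1 at least 2.5-fold. EPHB1 was 2.24-fold, C1GALT1C1 1.87-fold and PRR15L 1.82-fold lower. The second probe of C1GALT1C1 had a log2 difference of -0.27.

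The HSF1 heat shock targets rose as a group: 7 of 24 measured members were called, all higher, 15 adjusted over the list alone, and the median log2 difference was 0.84 (camera adjusted p = 4.04e-30, and adjusted p = 7.75e-05 with an estimated correlation). DNAJB1, another member, had a log2 difference of 3.84 and an adjusted p of 0.0815. The ATF4 integrated stress response genes were higher as a group, with a median of 0.40 (adjusted p = 4.33e-13; 0.0032 with an estimated correlation), 1 of 31 called (TRIB3, 2.21-fold) and 11 adjusted over the list alone. The immediate early genes had a median of 0.60 (adjusted p = 1.12e-09; 0.00209 with an estimated correlation, and 0.194 without GR3KR 15d-PGJ2 arrays 1 and 2 and with the index), with 1 of 20 called (DUSP1, 2.31-fold) and 4 adjusted over the list alone. DUSP1 encodes a phosphatase of MAP kinases and is also a glucocorticoid receptor target.

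Another 3 lists were called by camera, and none of them held with an estimated correlation. The NF-kB targets had a median of 0.38 (adjusted p = 2.48e-06; adjusted p = 0.205 with an estimated correlation). Limma called 0 of their 16 members, 6 had an unadjusted p under 0.05 and 3 were higher adjusted over the list alone; TNFAIP3 had a log2 difference of 0.89 (adjusted p = 0.171) and IER3 one of 0.76 (adjusted p = 0.239). The NRF2 targets had a median of 0.05 (adjusted p = 0.0206; adjusted p = 0.285 with an estimated correlation), with 2 of 24 called over all genes and over the list alone, HMOX1 and SQSTM1 (2.23-fold). Without wtGR dexamethasone array 3 or wtGR 15d-PGJ2 array 3 their adjusted p was 0.0698 and 0.109, and 0.133 with the index over 12 arrays. The glucocorticoid receptor targets had a median of 0.003 (adjusted p = 0.0162; adjusted p = 0.205 with an estimated correlation), with DUSP1 alone of 33 called over all genes and 6 higher and 2 lower adjusted over the list alone; their adjusted p was 0.157 without GR3KR 15d-PGJ2 arrays 1 and 2 and with the index, 0.0714 with array weights and 0.0825 under median scaling. Under median scaling the medians of these last lists were -0.20 and -0.17, where the median of all genes was -0.29.

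Over all genes, 27 of 12337 were called, 18 higher and 9 lower, and 1212 had an unadjusted p under 0.05; 66.7% of the calls were higher, 42.9% under median scaling. Treated and control arrays did not overlap in 2601 genes, 21.1% where chance gives 10%. The count fell to 6 without wtGR dexamethasone array 2 or wtGR 15d-PGJ2 array 1 or 2, to 13 without wtGR dexamethasone array 1, to 14 without wtGR 15d-PGJ2 array 3 or GR3KR dexamethasone array 3 and to 17 without GR3KR dexamethasone array 2, and rose to 44 and 110 without GR3KR 15d-PGJ2 array 1 and 3. Of 22 named calls, 6 (HSPA6, HSPA7, HSPA1A, HMOX1, MIR503HG and KCNA5) held in each of the 12 fits that leave out an array. The 27 genes were all called in the same direction with the index over 12 arrays (163 calls). Leaving out GR3KR 15d-PGJ2 arrays 1 and 2 cannot change a log2 difference between the wtGR groups, only its error.

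**Figure D2:**
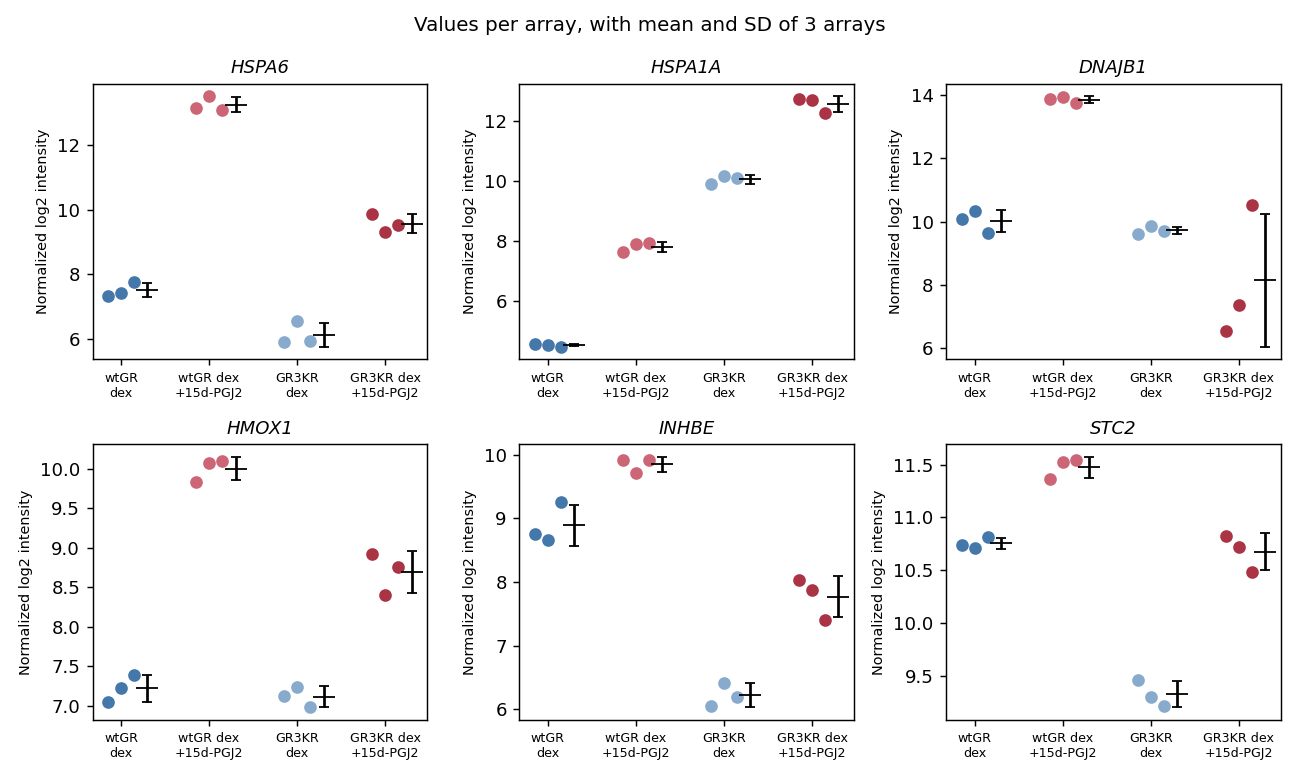
Log2 normalized intensity of HSPA6, HSPA1A, DNAJB1, HMOX1, INHBE and STC2 by group, each point an array, with the mean and SD of 3 arrays. HSPA6 reaches 13.25 in wtGR cells with 15d-PGJ2 and 9.57 in GR3KR cells with 15d-PGJ2, and INHBE starts at 8.89 in wtGR and at 6.22 in GR3KR cells.

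In GR3KR cells, 15d-PGJ2 also raised HSPA6, HSPA1A and HMOX1. It raised HSPA1L too, which was not among the increases named in wtGR cells. HSPA6 rose 10.9-fold, from 6.13 ± 0.36 to 9.57 ± 0.28 (SD, n = 3; limma adjusted p = 7.44e-05). Its second probe was below detection on all 6 GR3KR arrays, and above it on all 3 wtGR arrays with 15d-PGJ2, so that probe does not show the rise in GR3KR cells. HSPA1A rose 5.72-fold (log2 difference 2.52, SE 0.17), HSPA1L 5.02-fold and HMOX1 2.99-fold. Without arrays 1 and 2 of the treated group, their log2 differences were 3.42, 2.21, 1.86 and 1.64, with adjusted p of 0.00658, 0.00658, 0.0269 and 0.0221, and with the index as well all 4 were called (3.18, 2.13, 1.88 and 1.42). With the index as a covariate over 12 arrays they were 3.09, 2.10, 1.75 and 1.38, and none of the 4 passed, with adjusted p of 0.104, 0.082, 0.351 and 0.421.

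The other named increases were TEX19 (5.06-fold), MIR98 (at least 3.67-fold), B4GALT1 (5.04-fold), SNHG8 (4.7-fold), LINC00526 (at least 4.37-fold), TMEM68 (at least 3.71-fold) and PLEKHO2 (at least 3.88-fold). The named decreases were of the translation factor EEF1G (65.4-fold), CYBA, a subunit of NADPH oxidase (at least 46.8-fold), the glycolytic PGAM1 (at least 30.3-fold), PRMT1 (at least 29.4-fold), AHCY (at least 29.3-fold), LGALS3BP (at least 18.3-fold), GPAA1 (at least 18.2-fold), MRPL12 (at least 16.3-fold), KPNA2 (at least 13.4-fold) and PKMYT1 (at least 12.1-fold). All of these decreases but EEF1G rest on a treated group with 1 array or none above detection. Of these 17 genes, TEX19 and CYBA were also called without arrays 1 and 2, TEX19, CYBA, MIR98 and AHCY with the index as well, and none with the index over 12 arrays. AHCY read 6.85 ± 3.47 in the treated group. Second probes had log2 differences of 0.71 for KPNA2, -1.19 for PGAM1 (detected on all arrays) and -2.59 for PKMYT1 (detected on 1 treated array). The folds are therefore of the probe in use, and they are over all arrays, not those of the alternatives.

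Camera called none of the 20 tested lists in GR3KR cells over all arrays (lowest adjusted p 0.62). Fry, which makes no comparison with other genes, called lists higher there. Among them were the HSF1 targets (adjusted p = 0.000106), the ATF4 genes (0.000347) and the glucocorticoid receptor targets (0.00226). The median of all genes was itself 0.26 in this effect. In the alternatives for array quality camera called some lists. The HSF1 targets had a median of 0.39 and an adjusted p of 0.0513 without arrays 1 and 2 of the treated group, 0.50 and 1.82e-06 with the index as well, and 0.47 and 6.7e-09 with the index over 12 arrays; with an estimated correlation the adjusted p was 0.508, 0.2 and 0.0308. The ATF4 genes had medians of 0.48, 0.31 and 0.43 in these settings, with an adjusted p of 0.0273, 0.000167 and 4.27e-05, and 0.508, 0.148 and 0.102 with an estimated correlation. The NRF2 targets had an adjusted p of 0.0499 with the index over 12 arrays, and 0.651 with an estimated correlation.

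Over all arrays, of the HSF1 targets 9 were called higher and 2 lower of 24, over all genes and over the list alone. CACYBP was at least 9.61-fold lower, and its second probe had a log2 difference of -1.12. Of the ATF4 genes 13 were higher and 2 lower of 31 (13 and 3 over the list alone). INHBE rose 2.93-fold, GDF15 2.88-fold and STC2 2.55-fold, while ATF3 was 5.33-fold lower. The second probe of ATF3, below detection on all GR3KR arrays, had a log2 difference of -0.02. The NF-kB targets had 5 higher and 1 lower of 16 (4 and 1 over the list alone), with NFKBIE 2.07-fold, TNFAIP3 1.87-fold and IRF1 1.86-fold higher, and CXCL8 higher with no fold since 1 of the 3 treated arrays lay below detection. The immediate early genes had 5 higher and 6 lower of 20 (7 and 6 over the list alone). IER5 was 2.86-fold lower, and MYC at least 2.92-fold lower by 1 probe against a log2 difference of 1.72 by its second. FOS was called lower, but its 3 treated arrays lay below detection. No difference was left once they were raised to the lowest detected level, so a fall of FOS was not measured. The NRF2 targets had 6 higher and 5 lower of 24 (7 and 6 over the list alone), with FTL 19.4-fold, MAFG at least 2.37-fold and PGD 2.86-fold lower, and a median of 0.27 against a mean of -0.11. The glucocorticoid receptor targets had 10 higher and 2 lower of 33 (9 and 2 over the list alone), among them ARRDC2 (2.56-fold, and 0.54 on the log2 scale by its second probe), GADD45B (2.28-fold), SCNN1A (2.13-fold) and ZBTB16 (2.1-fold). Of the members named here, STC2 and FTL were also called without arrays 1 and 2, with and without the index, and none with the index over 12 arrays. The fold of FTL is over all arrays. Its second probe read 7.23 and 7.17 on GR3KR 15d-PGJ2 arrays 1 and 2 and 11.71 on array 3, against 13.27 to 13.44 on GR3KR dexamethasone arrays. Much of the fall by that probe thus rests on arrays 1 and 2.

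Over all genes, 5608 were called, 3782 higher and 1826 lower, and 6836 had an unadjusted p under 0.05. The share of higher calls was 67.4%, 52% under cyclic loess and 44.3% under median scaling. Arrays of the groups did not overlap in 6672 genes, 54.1% where chance gives 10%. Of 1447 called genes with a second kept probe, that probe moved the same way in 786, or 54.3%. The count was 60 without arrays 1 and 2, 209 with the index as well, and 0 with the index over 12 arrays, where limma left 550 genes at an unadjusted p under 0.05. It was 2532 and 3251 without GR3KR dexamethasone array 1 and 3, and 2969 and 2578 without GR3KR 15d-PGJ2 array 1 and 2. With the index over 12 arrays the median standard error was 0.339, against 0.246 without it, since the index did not overlap between these groups. The count of 0 in that setting therefore does not measure a lack of response. Of the 40 named calls 31 held whichever array was left out, and none in all 3 alternatives for array quality.

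The responses of both lines shared 13 of the higher calls (5.52 by chance) and 2 of the lower (1.33 by chance), and 2 genes were called in opposite directions. Across the 12337 genes the effects correlated at -0.311 (Pearson) and -0.233 (Spearman). The Pearson value was 0.057 without wtGR dexamethasone array 3, 0.01 with the index over 12 arrays and -0.06 with the index and without GR3KR 15d-PGJ2 arrays 1 and 2. It was -0.348 without those GR3KR arrays alone, and -0.442 without wtGR dexamethasone array 1.

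The difference of the effects asks whether the response differs between the lines, and with 1 line for each receptor form it cannot separate the receptor from other differences between them. Over all arrays, some heat shock genes had a difference of effects below 0. HSPA1B had a log2 difference of -4.49 (SE 0.63, limma adjusted p = 0.00864) and DNAJB1 one of -5.42 (SE 1.06, adjusted p = 0.0165). STIP1 had -2.31 and CACYBP -7.28. For HSPA1B, DNAJB1 and CACYBP the difference was larger than the rise in wtGR cells. Their estimates in GR3KR cells were thus falls, not smaller rises. CACYBP was above detection on 1 GR3KR array with 15d-PGJ2, and its second probe differed by -1.51. HSPA6, chosen after its values were seen, differed by -2.29 (SE 0.32, adjusted p = 0.00864), from a rise of 5.74 in wtGR to 3.45 in GR3KR cells, and HMOX1, chosen likewise, by -1.20 (adjusted p = 0.0181). Without GR3KR 15d-PGJ2 arrays 1 and 2, DNAJB1 stayed called (-3.04, adjusted p = 0.0249), while HSPA6 differed by -2.32 with an adjusted p of 0.0561, HMOX1 by -1.14 with 0.0842 and HSPA1B by -3.82 with 0.0727. With the index as well all 4 were called: DNAJB1 at -2.74 (adjusted p = 0.0222), HSPA6 at -2.66 (0.0334), HMOX1 at -1.45 (0.0427) and HSPA1B at -2.20 (0.0427). With the index over 12 arrays none of them was, at -1.67, -2.72, -1.44 and -2.31, with adjusted p of 0.9, 0.614, 0.86 and 0.86. STIP1 and CACYBP were called in none of these 3 settings: STIP1 had -1.37, -1.45 and -0.98 (adjusted p = 0.0727, 0.0725 and 0.89) and CACYBP -6.51, -1.32 and -1.76 (0.147, 0.0892 and 0.947).

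The HSF1 targets had a median difference of -0.52 (camera adjusted p = 0.00024; adjusted p = 0.0635 with an estimated correlation), with 1 of 24 higher (HSPA1L, 1.71, adjusted p = 0.0154, chosen after its value was seen) and 9 lower, and 2 and 11 adjusted over the list alone. Under median scaling their median was -0.21, with an adjusted p of 0.119. The immediate early genes had a median of -0.66 (adjusted p = 0.00828; adjusted p = 0.101 with an estimated correlation), with 1 of 20 higher and 7 lower (2 and 8 over the list alone): MYC differed by -3.95 by 1 probe and by 1.13 by its second, ATF3 by -3.40, IER5 by -2.50 and FOS by -1.82. The second probe of ATF3, below detection on all GR3KR arrays, differed by -1.16. With 15d-PGJ2 in GR3KR cells, MYC was detected on 1 array and FOS on none. None of these 4 genes was called in the 3 alternatives for array quality. The list's adjusted p was 0.0502 without GR3KR 15d-PGJ2 array 3 and 0.0808 with the index over 12 arrays, and 0.109 without arrays 1 and 2 and with the index. The glucocorticoid receptor targets were not called (adjusted p = 0.873): 4 of 33 were higher and 2 lower, over all genes and over the list alone, with CRISPLD2 at 1.55, ARRDC2 at 1.35, DUSP1 at -1.23 and NFKBIA at -0.99, of which those alternatives called none. Their median of 0.24 and mean of 0.22 were above 0 and below the median of all genes, 0.33, and camera's direction was down. The NF-kB targets, not called over all arrays (adjusted p = 0.521), were called lower with the index over 12 arrays (median -0.52, adjusted p = 0.000358) and with the index and without arrays 1 and 2 (-0.47, 0.0077), where the estimated correlation gave an adjusted p of 0.334 and 0.92.

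The named positive differences were of AS3MT (2.73), SEMA3B (2.72), PLEKHO2 (2.63), B4GALT1 (2.62), MIR98 (2.52), TMEM68 (2.52), WNK4 (2.50) and MAFA-AS1 (2.49). The named negative ones, besides CACYBP, were of PGAM1 (-7.61, and -2.51 by its second probe), EEF1G (-7.51), CYBA (-7.05), PRMT1 (-6.89), PKMYT1 (-6.68, and -2.72 by its second probe), PI4KAP1 (-6.63) and KPNA2 (-6.61), whose second probe had 1.5. With 15d-PGJ2 in GR3KR cells, all of these negative ones but EEF1G had 1 array or none above detection, so their sizes and order are not measured. The same holds for the positive ones of SEMA3B, PLEKHO2, MIR98, TMEM68 and MAFA-AS1, which had at most 1 array above detection in wtGR cells with 15d-PGJ2. Of these 16 genes, CYBA was called without GR3KR 15d-PGJ2 arrays 1 and 2 (-5.49, adjusted p = 0.036), and with the index as well (adjusted p = 0.000797). Over all genes 3044 were called, 2172 higher and 872 lower, and 5483 had an unadjusted p under 0.05. The share of higher calls was 71.4%, and 51.9% under cyclic loess. The count was 24 without those arrays, 64 with the index as well and 0 with the index over 12 arrays, where limma left 690 at an unadjusted p under 0.05. Leaving out 1 array gave 1475 and 723 (wtGR dexamethasone 2 and 3), 209 and 127 (wtGR 15d-PGJ2 1 and 2), 330, 1951 and 321 (GR3KR dexamethasone 1, 2 and 3), and 1277, 380 and 6502 (GR3KR 15d-PGJ2 1, 2 and 3). Of the 27 named calls 4 held whichever array was left out (AS3MT, MAFA-AS1, CYBA and HSPA1B).

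Without 15d-PGJ2, the lines differed in genes of the integrated stress response, among others. GR3KR cells had at least 26.7-fold more HSPA1A (10.05 ± 0.14 against 4.52 ± 0.04, SD, n = 3; limma adjusted p = 3.17e-08), at least 8.04-fold more of the growth hormone receptor GHR and at least 8.08-fold more of the transcription factor ISL1. The glutathione transferases GSTP1, GSTM1 and GSTM2 were 6.2-fold, 5.13-fold and 5.12-fold higher, CYP27A1 6.04-fold and PLAGL1 at least 3.38-fold. LCP1, an actin-bundling protein, was 33.5-fold lower (log2 difference -5.07, SE 0.34, adjusted p = 1.33e-05) and CRMP1 at least 24-fold lower. TENM1 was at least 13.6-fold, AMBN at least 8.84-fold, LY6G6D at least 7.95-fold, BEX5 at least 7.04-fold, PCDH19 at least 5.69-fold and ZNF700 at least 11-fold lower. Each of these 16 genes was called in all 12 fits that leave out an array. The fold of HSPA1A was not shared by heat shock genes in general. Of the 24 HSF1 targets, 3 were called higher, HSPA1A among them, and 2 lower. Camera did not call this list (adjusted p = 0.183), and fry called it higher (adjusted p = 0.000941). HSPA6, chosen after its values were seen, had a log2 difference of -1.39.

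The ATF4 integrated stress response genes were lower in GR3KR cells: 19 of 31 were called, all lower, 22 adjusted over the list alone, with a median of -0.95 (camera adjusted p = 2.46e-15; adjusted p = 0.00519 with an estimated correlation). INHBE was 6.36-fold, CHAC1 at least 3.13-fold, asparagine synthetase ASNS 3-fold and STC2 2.69-fold lower. The ER chaperones were lower in 6 of 16, over all genes and over the list alone (median -0.47, adjusted p = 0.00326; 0.0436 with an estimated correlation), with HSPA5 2.49-fold, DNAJB9 2.3-fold, DNAJC3 at least 1.89-fold and PDIA4 1.68-fold lower. The immediate early genes were lower in 4 of 20, on both counts (median -0.54, adjusted p = 0.00154; 0.0436 with an estimated correlation), with FOS 3.65-fold, KLF4 2.28-fold, FOSB 1.97-fold and DUSP1 1.68-fold lower. The canonical histones were higher in 6 of 9, on both counts (median 0.96, adjusted p = 5.58e-07; 0.00527 with an estimated correlation), with H1-2 3.34-fold, H2AC6 at least 1.6-fold, H2BC5 2.08-fold and H2BC4 at least 1.71-fold higher. With an estimated correlation the ATF4 genes also passed in the 3 alternatives for array quality. The ER chaperones did not without GR3KR 15d-PGJ2 arrays 1 and 2 (adjusted p = 0.0679) and with the index as well (0.0894), nor did the immediate early genes (0.145 and 0.179), nor the histones in the second of these (0.0892). By camera's preset correlation all 4 lists were called in each.

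The NF-kB targets had 7 of 16 lower, 12 adjusted over the list alone (median -0.78, adjusted p = 1.62e-07; adjusted p = 0.0906 with an estimated correlation): RELB was 3.55-fold, CCL20 at least 2.04-fold, TNF at least 1.39-fold and CXCL1 at least 1.33-fold lower. The glucocorticoid receptor targets had 8 of 33 lower, and 1 higher and 11 lower adjusted over the list alone (median -0.45, adjusted p = 0.00154; adjusted p = 0.0769 with an estimated correlation), among them CEBPB (2.43-fold), GADD45B (2.28-fold), ARRDC2 (2.15-fold) and PHACTR3 (2.07-fold). The second probe of ARRDC2 had a log2 difference of -0.04, and that of PHACTR3 one of -0.47. The neuronal markers, which HEK293-derived cells also express, had 4 of 9 lower and 5 adjusted over the list alone (median -0.89, adjusted p = 0.000893; adjusted p = 0.125 with an estimated correlation), with INA 3.34-fold, TUBB3 1.85-fold, STMN2 at least 2.4-fold and SYP at least 1.69-fold lower. The G2/M genes had 2 of 20 higher, CCNB1 (1.73-fold) and BUB1 (1.59-fold), and 4 over the list alone (median 0.24, adjusted p = 0.00326; adjusted p = 0.0663 with an estimated correlation).

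The sterol synthesis genes had a median of 0.34 (camera adjusted p = 0.0382; adjusted p = 0.125 with an estimated correlation). Limma called 0 of their 18 members, over all genes and over the list alone, with 3 at an unadjusted p under 0.05; MSMO1 had a log2 difference of 0.51 (adjusted p = 0.113) and SC5D one of 0.53 (adjusted p = 0.15). Their adjusted p was 0.0521 without wtGR dexamethasone array 1, 0.0745 without its array 3, 0.0673 under cyclic loess and 0.173 with the index over 12 arrays.

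Over all genes, 995 were called, 313 higher and 682 lower, and 2797 had an unadjusted p under 0.05. The share of higher calls was 31.5%, and 9.1% under median scaling, where the median of all genes was -0.22. The lines did not overlap in 4407 genes, 35.7% where chance gives 10%. A second kept probe moved the same way in 192 of 222 called genes, or 86.5%. All 995 were called in the same direction without GR3KR 15d-PGJ2 arrays 1 and 2, with the index, and with both (2194, 2176 and 4644 calls). The count was 526 and 637 without wtGR dexamethasone array 2 and 3, 395, 477 and 395 without GR3KR dexamethasone array 1, 2 and 3, and 1785 without GR3KR 15d-PGJ2 array 3. Of the 46 named calls 32 held whichever array was left out. Each receptor form was measured in 1 line, so the receptor and other differences between the lines cannot be separated here.

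**Figure D3:**
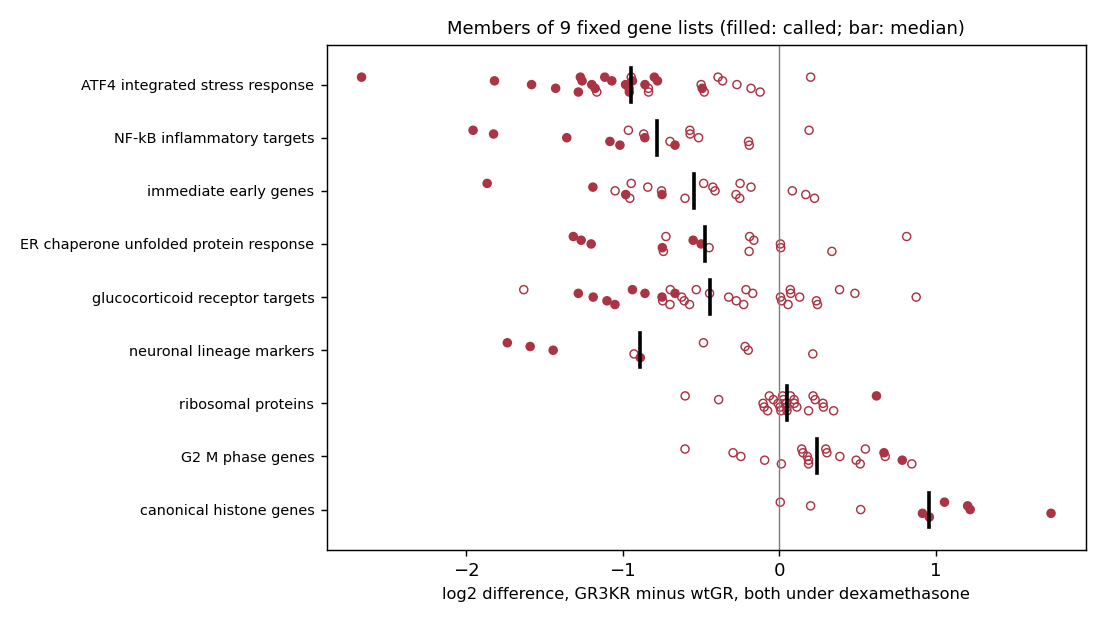
Log2 difference of GR3KR minus wtGR cells under dexamethasone for members of 9 fixed gene lists, each point a gene, filled where called, with a bar at the list median. The ATF4 list has a median of -0.95 with 19 of 31 called lower, and the canonical histones one of 0.96 with 6 of 9 called higher.

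With 15d-PGJ2, many of the differences between the lines were called again. HSPA1A was 27.2-fold higher in GR3KR cells (12.56 ± 0.26 against 7.80 ± 0.16, SD, n = 3; limma adjusted p = 1.61e-07), GHR at least 10.8-fold, ISL1 at least 11.8-fold, GSTM1 12.3-fold, GSTM2 10-fold, the neural adhesion protein CNTN1 at least 8.99-fold, HSPA1L at least 8.15-fold and STAT6 at least 7.59-fold. All 8 were also called in the 3 alternatives for array quality. The second probe of GSTM2 was detected on all 3 GR3KR arrays without 15d-PGJ2 and on none of the GR3KR or wtGR arrays with it, so it does not show the difference. Of the named decreases, CYBA (at least 34.9-fold) was called in all 3, AHCY (at least 34.9-fold) and DNAJB1 (52.2-fold) in all but the index over 12 arrays (adjusted p = 0.886 and 0.186), HDGFL2 (at least 18.1-fold) without arrays 1 and 2, and EEF1G (59.8-fold), PGAM1 (at least 23.5-fold), CACYBP (at least 24.3-fold) and RNA28SN5 (at least 16.2-fold) in none. These folds are over all arrays, not those of the alternatives. Second probes had log2 differences of -1.64 for PGAM1, -2.05 for HDGFL2 and -0.81 for CACYBP.

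The ATF4 genes had 21 of 31 lower and 23 adjusted over the list alone (median -0.96, camera adjusted p = 3.49e-10, and 0.0162 with an estimated correlation). ATF3 was 20.3-fold, CHAC1 at least 2.3-fold, DDIT3 4.46-fold and INHBE 4.22-fold lower. The second probe of ATF3, below detection on all GR3KR arrays, had a log2 difference of -1.45. The immediate early genes had 10 of 20 lower, on both counts (median -0.65, adjusted p = 3.24e-05; 0.0162 with an estimated correlation), with MYC at least 16.1-fold lower by 1 probe and -0.44 on the log2 scale by its second, IER5 6.74-fold and FOS at least 4.62-fold lower. With an estimated correlation the list's adjusted p was 0.0605 without GR3KR 15d-PGJ2 arrays 1 and 2 and 0.116 with the index as well. The HSF1 targets had 4 of 24 higher and 10 lower, and 4 and 11 over the list alone. Their median was -0.32 (camera adjusted p = 0.0278, and 0.167 with an estimated correlation), with HSPA1B 18-fold lower. HSPA1A, its near copy, was higher, so the probes of these near-identical genes moved opposite ways. The ER chaperones had 2 of 16 higher and 7 lower (2 and 8 over the list alone; median -0.51, adjusted p = 0.0161; adjusted p = 0.0894 with an estimated correlation), with EDEM1 at least 5.64-fold, PDIA6 at least 6.95-fold, HYOU1 at least 3.31-fold and XBP1 4.64-fold lower. Without GR3KR 15d-PGJ2 array 3 the adjusted p of these last lists was 0.0827 and 0.0565, and under median scaling 0.57 and 0.0938, and the first had 0.124 with the index over 12 arrays. The NF-kB targets had 2 of 16 higher and 9 lower, on both counts (median -0.63, adjusted p = 0.000844; adjusted p = 0.29 with an estimated correlation), with RELB at least 2.95-fold, CCL20 at least 1.79-fold and TNF at least 1.36-fold lower.

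The glucocorticoid receptor targets had a median of -0.24 and were not called over all arrays (camera adjusted p = 0.0893), with 7 of 33 higher and 10 lower on both counts; IRS2 was at least 5.32-fold, DUSP1 3.94-fold, NFKBIA 3.14-fold and DDIT4 2.98-fold lower. They were called lower in all 3 alternatives for array quality: the adjusted p was 0.00607 without arrays 1 and 2 (median -0.08), 0.00884 with the index as well (-0.45) and 0.0019 with the index over 12 arrays (-0.45). With an estimated correlation they passed in the last alone (adjusted p = 0.115, 0.07 and 0.0235). All 3 alternatives also called the sterol synthesis genes, G2/M genes and histones higher and the neuronal markers lower (highest adjusted p 0.0223, 0.0286, 0.00607 and 0.0216), where over all arrays the adjusted p was 0.528, 0.117, 0.117 and 0.299. With an estimated correlation the G2/M genes, histones and neuronal markers passed with the index over 12 arrays alone (adjusted p = 0.0377, 0.0235 and 0.0319), and the sterol synthesis genes in none.

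Over all genes, 6340 were called, 4037 higher and 2303 lower, and 7256 had an unadjusted p under 0.05. The share of higher calls was 63.7%, 51% under cyclic loess and 50.3% under median scaling. The lines did not overlap in 6793 genes, 55.1% where chance gives 10%. A second kept probe moved the same way in 56.3% of called genes. The count was 2213 without GR3KR 15d-PGJ2 arrays 1 and 2, 2135 with the index as well and 306 with the index over 12 arrays. Of the 35 named calls 34 held whichever array was left out (RNA28SN5 did not), and 14 in all 3 alternatives for array quality. With and without 15d-PGJ2 the lines shared 241 higher calls (102 by chance) and 325 lower calls (127 by chance), and 32 genes were called in opposite directions. The differences correlated across genes at 0.104 (Pearson) and 0.152 (Spearman).

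Over the 5 comparisons and 20 lists, camera called 22 of 100 tests, of which 9 held with an estimated correlation and 18 by fry. Between-array scaling shifted the median of all genes. In the wtGR effect, the GR3KR effect, their difference, and the lines without and with 15d-PGJ2 it was -0.07, 0.26, 0.33, -0.03 and 0.21 by quantile normalization, -0.01, 0.07, 0.08, 0.02 and -0.01 by cyclic loess, and -0.29, 0.09, 0.37, -0.22 and 0.04 by median scaling.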

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

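Of the tests in this part, the direction of second probes and the regroupings of arrays were set before the results they measure were seen, and the tests on second probes detected throughout, on calls left without both arrays, on the heat shock difference and on the level of these genes before 15d-PGJ2 were chosen after, the heat shock test being made stricter (to need an estimated correlation too) when its values were known.

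The response to 15d-PGJ2 differed between GR3KR and wtGR cells in 3044 genes by the test of the difference itself. Of these, 742 had a second kept probe, which moved the same way in 424, or 57.1%. Of 100 drawn regroupings of the arrays within each line, 2 gave as many calls, the real one included. That is a share under 0.05, and the highest other gave 3362. Regrouping mostly mixes treated and control arrays in each line, so it asks whether either line responded. It does not test the 3044 calls against equal responses in both lines. The calls come with 5608 in the 15d-PGJ2 effect in GR3KR cells, where 1 of the 10 regroupings of the 6 arrays gave as many and the highest other gave 0, and 10 regroupings are too few for a share under 0.05.

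For the 5608 calls in GR3KR cells, the lower quality of GR3KR 15d-PGJ2 arrays 1 and 2 is a candidate explanation. If it were the cause, second probes of called genes would often move the other way, and 54.3% of 1447 genes had a second probe that moved the same way, against 86.5% of the genes called between the lines under dexamethasone. Where the second probe was detected on all arrays compared, these were 64.8% of 579 and 88.7% of 151, so part of the disagreement may come from probes near background. A response of the GR3KR cells stays open for part of the calls: without both arrays and with the index, 163 of 5608 were called in the same direction. That setting leaves 1 array in the group, assumed to vary like the others, so the loss of calls does not measure how many were technical.

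The HSF1 heat shock targets had a median difference of effects of -0.52, which would be a smaller response in GR3KR cells. The median was -0.56 without both arrays, -0.60 with the index as well and -0.64 with the index over 12 arrays. The list was called in each at camera's preset correlation. Array 3, the only one of its group left without both arrays, had the lowest index of the 10 arrays (-0.521). It also detected the fewest probes of them (17032). These medians therefore do not separate a smaller response from array quality. With an estimated correlation the list passed in none of the 3 settings (adjusted p = 0.194 with the index over 12 arrays), so the test did not exclude array quality. It had already failed over all arrays (adjusted p = 0.0635), before any adjustment for quality. The failure is thus no evidence that quality caused the shift. A higher level of these genes before 15d-PGJ2 could leave less room for a rise, and their median difference between the lines under dexamethasone was 0.018, with a standard deviation of 1.33 over members, against a shortfall of 0.523. With members this far apart the median does not decide, and a role of receptor SUMOylation stays open and untested.

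The immediate early genes had a median difference of effects of -0.66 (camera adjusted p = 0.00828, and 0.101 with an estimated correlation). It was -0.68 without both arrays (adjusted p = 0.00017), -0.45 with the index as well (0.109) and -0.17 with the index over 12 arrays (0.0808). Among the heat shock genes, the log2 difference of effects was -7.28 for CACYBP (-1.51 by its second probe), -5.42 for DNAJB1, -4.49 for HSPA1B and -2.31 for STIP1. Among the immediate early genes, it was -3.95 for MYC (1.13 by its second probe), -3.40 for ATF3 (-1.16 by its second probe), -2.50 for IER5 and -1.82 for FOS. With 15d-PGJ2 in GR3KR cells, CACYBP and MYC had 1 array above detection and FOS none, so these sizes are not measured. Among glucocorticoid receptor targets it was 1.55 for CRISPLD2, 1.35 for ARRDC2, -1.23 for DUSP1 and -0.99 for NFKBIA. The named positive differences were 2.73 for AS3MT, 2.72 for SEMA3B, 2.63 for PLEKHO2, 2.62 for B4GALT1, 2.52 for MIR98, 2.52 for TMEM68, 2.50 for WNK4 and 2.49 for MAFA-AS1. The named negative ones were -7.61 for PGAM1 (-2.51 by its second probe), -7.51 for EEF1G, -7.05 for CYBA, -6.89 for PRMT1, -6.68 for PKMYT1 (-2.72 by its second probe), -6.63 for PI4KAP1 and -6.61 for KPNA2 (1.5 by its second probe). All of these negative ones but EEF1G had 1 array or none above detection in GR3KR cells with 15d-PGJ2, and the positive ones of SEMA3B, PLEKHO2, MIR98, TMEM68 and MAFA-AS1 at most 1 in wtGR cells with it, so their sizes and order are not measured.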

How the results depend on the processing

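The alternatives that leave out GR3KR 15d-PGJ2 arrays 1 and 2 or use the probe disagreement index were chosen after seeing the data; all others were set beforehand. Unless stated, the cause of a change was not tested. Counts of genes, lists and named results under an alternative not named here stayed within 1.5 times those reported. Signal over background limits the GR3KR 15d-PGJ2 group most, with the lowest detected level at a log2 intensity of 6.15 and 6.44 on its arrays 1 and 2 and between 5.20 and 5.70 on the other 10. Leaving an array out also leaves fewer arrays, and a stricter threshold calls fewer genes by construction.

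The 27 calls of the wtGR 15d-PGJ2 effect became 56 with lumi values, 48 with cyclic loess, 14 with median scaling, 45 with no filter, 44 with trend and robust, 105 with array weights (which ran from 0.0484 to 18.3 when the iteration stopped), 11 with the replicate block, 11 with only the groups of the comparison and 8 at an adjusted p under 0.01; every kept probe gave 16. The 5608 calls in GR3KR cells became 9371 with every kept probe, 3431 with array weights, 3132 with only the groups and 1550 at 0.01. The 3044 calls of the difference became 1494 with cyclic loess, 4948 with every kept probe and 41 at 0.01. The 995 calls between the lines became 2128 with array weights and 340 at 0.01, and the 6340 with 15d-PGJ2 became 10607 with every kept probe and 3828 at 0.01. The replicate block gave 5451, 2225, 781 and 6373 in the last 4 comparisons, 22 lists and 155 named results. Replicate numbers did not pair the arrays: deviations from the group means correlated between -0.671 and 0.705 over the 18 pairs of arrays with the same number, and 5 of the 12 arrays lay closest to one of their own number in another group.

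Without both arrays, the 5 counts were 153, 60, 24, 2194 and 2213. With the index over 12 arrays they were 163, 0, 0, 2176 and 306, where limma left 550 and 690 genes at an unadjusted p under 0.05 in the counts of 0. With both they were 1152, 209, 64, 4644 and 2135. Of the 170 called named results, 107, 82 and 109 were called in these settings, and 105 at an adjusted p under 0.01. The 22 called lists became 9 with an estimated correlation and 39 with fry.

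The correlation of effects (-0.311) was -0.447 with every kept probe, -0.348 without both arrays, -0.06 without both arrays and with the index, and 0.01 with the index over 12 arrays. Leaving out each array gave -0.442 to 0.057 for the correlation, 6 to 110 calls in wtGR cells, 2532 to 7691 in GR3KR cells, 127 to 6502 for the difference, 395 to 1785 between the lines, 4714 to 7837 with 15d-PGJ2, 19 to 25 lists and 127 to 169 named results.

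These named genes changed sign, in log2. With the index over 12 arrays, the effect in GR3KR cells was -0.15 for SCNN1A, 0.33 for CACYBP, 0.51 for ATF3, -0.029 for GDF15, 1.21 for MYC and 0.50 for IER5, the difference of effects 0.53 for MYC and 0.089 for ATF3, and the difference between lines with 15d-PGJ2 0.15 for RNA28SN5 and 0.45 for PDIA6. Without both arrays and with the index, the effect in GR3KR cells was 0.12 for CACYBP, 0.12 for ATF3, 0.62 for MYC and 0.20 for IER5, and the difference between lines 1.17 for RNA28SN5 and 0.44 for PDIA6. Without both arrays the effect on MYC was 0.19. No named gene changed sign under cyclic loess or median scaling.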

Other observations

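In this part, the regroupings of arrays were set before their results were seen, and the tests of array quality and of receptor targets between the lines were chosen after.

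The SUMO machinery, which conjugates and removes the modifier that the mutant receptor cannot accept, did not pass in wtGR cells with 15d-PGJ2: limma called 0 of 12 measured members, 1 had an unadjusted p under 0.05, 1 was higher adjusted over the list alone, and camera gave an adjusted p of 0.855. Between the lines under dexamethasone limma called 0 of 12, with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.473). Limma called 2 higher and 3 lower in the GR3KR effect, 2 and 1 in the difference, and 5 and 3 between the lines with 15d-PGJ2. Of all genes, 45.5%, 24.7% and 51.4% were called there, and the list did not pass (camera adjusted p = 0.792, 0.873 and 0.903). PPAR targets, listed because 15d-PGJ2 binds PPAR gamma, had 0 of 11 called by limma in wtGR cells and 1 at an unadjusted p under 0.05 (adjusted p = 0.439), and 0 of 11 and 4 between the lines (adjusted p = 0.882), where 1 was higher and 2 lower adjusted over the list alone. The p53 targets had 0 of 17 called in wtGR cells, with 7 at an unadjusted p under 0.05 and 1 lower adjusted over the list alone (adjusted p = 0.855), and 2 higher between the lines, on both counts (adjusted p = 0.953). Proteasome subunits had 0 of 27 called in wtGR cells, with 1 at an unadjusted p under 0.05 (adjusted p = 0.855), and between the lines 1 higher and 3 lower, on both counts (adjusted p = 0.155).

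The metallothioneins had 0 of 6 called by limma in wtGR cells, with 1 at an unadjusted p under 0.05 and 1 lower adjusted over the list alone (camera adjusted p = 0.118), and 1 lower between the lines (1 higher and 1 lower over the list alone; adjusted p = 0.953). S phase genes had 0 of 20 called in wtGR cells, with 2 at an unadjusted p under 0.05 and 1 lower over the list alone (adjusted p = 0.478), and 1 higher between the lines (adjusted p = 0.618). Hypoxia targets had 0 of 13 called in both, with 2 and 3 at an unadjusted p under 0.05 (adjusted p = 0.322 and 0.834). The cytoskeletal targets of YAP and SRF had 0 of 14 called in both, with 0 and 2 at an unadjusted p under 0.05 (adjusted p = 0.911 and 0.678). Ribosomal proteins had 0 of 26 called in wtGR cells, with 1 at an unadjusted p under 0.05 (adjusted p = 0.439), and 1 higher between the lines (adjusted p = 0.408).

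Few markers of other cell types were measured. Of 10 fibroblast markers 2 were measured, COL1A1 and COL5A1, with group means from 6.27 to 7.94, and 1 was called, higher with 15d-PGJ2 in GR3KR cells. Of 10 leukocyte markers 3 were measured: CD14 from 6.81 to 7.86, CD68 from 8.86 to 9.85 and CORO1A from 4.53 to 6.15, with 1 called higher and 1 lower with 15d-PGJ2 in GR3KR cells. Both lists were too small for camera. Between the lines under dexamethasone, 0 of the 2 fibroblast markers were called by limma with 1 at an unadjusted p under 0.05, and 1 of the 3 leukocyte markers was called lower.

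The genes called between GR3KR and wtGR cells under dexamethasone were weighed against array quality and against the receptor form. All 995 of 995 calls stood in the same direction with the index as a covariate. The index overlapped between the lines, from -0.13 to 0.222 on wtGR and from 0.0901 to 0.242 on GR3KR dexamethasone arrays. The covariate thus had little to remove, and the result speaks only against a quality difference that the index measures. Of the glucocorticoid receptor targets 24.2% were called, against 8.07% of all genes. Their list was called lower by camera's preset correlation (adjusted p = 0.00154) and by fry (0.00134). With an estimated correlation it did not pass over all arrays (adjusted p = 0.0769). Among the alternatives for array quality it then passed with the index over 12 arrays alone (0.0442). Of the ATF4 genes, not picked for the receptor, 19 of 31 were called. A raised share of calls is therefore not particular to receptor targets, and a role of the receptor form stays open. With 1 line for each form, other differences between the lines cannot be told apart from it.

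In the wtGR 15d-PGJ2 effect, 2 of the 10 regroupings of the 6 arrays gave as many calls as the real one (27). The other, which set wtGR dexamethasone array 1 with wtGR 15d-PGJ2 arrays 1 and 2 against the rest, gave 213, several times the real count, and it follows the probe disagreement index, which is above 0.2 on these 3 arrays and below it on the other 3. With the index as a covariate 163 genes were called. Between the lines, 1 of the 10 regroupings gave as many calls both without 15d-PGJ2 (995) and with it (6340), and the highest other gave 0 in both. In each comparison 10 regroupings are too few for a share under 0.05.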
